A study of Ovis aries with 14 samples.

How the data were processed

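Hypothalamic RNA of fetal sheep at about day 130 of gestation was measured with single-colour (Cy3) Agilent ovine arrays. The labels list 14 arrays in 4 groups. In the direct arm the fetus itself was infused for 2 days with vehicle (n = 4) or with triclosan at 250 µg per day (n = 4). In the indirect arm the ewe was infused for 2 days with vehicle (3 deposited arrays) or with triclosan at 100 µg/kg per day (n = 3). Per the labels' protocols, RNA was extracted with Trizol, purified on RNeasy columns with DNase treatment, and labelled with Cy3. Whether the arrays of a group came from separate pregnancies is not given in the sources used here.

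Per the file headers, the authors' scanner files hold spot intensity values made by Agilent Feature Extraction 10.1.1.1, with a raw mean signal, a local background signal, and a processed signal that was background-subtracted and detrended within the array but not normalised between arrays. The deposited value table of the authors appears to be on a log2 scale, since each of its 14 columns lay closest to the log2 processed signal of its own array. Its columns had nearly equal distributions, with medians from 8.78 to 8.80 and a common maximum of 19.0, and it listed 13899 probes. Its exact scaling and its filter are not given in the sources used here. limma is named in the submitters' processing notes without a role or a version.

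Maternal vehicle replicate 3 as deposited was not an independent measurement. At all 15744 spots its processed, mean, median and background signals equalled 0.6 times those of replicate 1 plus 0.4 times those of replicate 2 of the same group, within a relative difference of 1e-06, and its quality flags equalled those of replicate 1 at all 15744 spots. No other array came near such a combination, with a median residual of at least 11.14%. The main analysis therefore used 13 arrays, with maternal vehicle at n = 2, and the fit of all 14 arrays is an alternative that was added after the data were seen.

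The log2 of the processed signal was taken and the 75th percentile of each array was subtracted. Control spots and spots with outlier marks were left out, spots of the same probe were averaged, and a probe was kept when it was well above background on at least 3 arrays, which left 13740 probes and 250 missing values. limma 3.58.1 in R 4.3.3 was fitted with a mean per group (9 residual and 2.36 prior degrees of freedom), and its two-sided moderated test was adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The 4 contrasts were direct exposure, indirect exposure, the difference between the arms, and maternal against fetal vehicle. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. A gene whose signal was not well above background on any array of a group has only a bound there, and the fold is then given as a lower bound, with each dim value raised to the lowest signal that was well above background on its array. Such a bound holds for the main processing only, and other processing can give a smaller fold.

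Probe names came from the scanner files and from the supplied gene table, matched through RefSeq transcript (726 probes), symbol (497), gene number (139) or older symbol (20), with 274 probes keeping the name in the file. Of 15008 probes, 1556 carried a gene symbol (964 symbols), 100 only a locus number, and 13352 no gene name. The named genes tested numbered 893, with the probe of the highest mean standing for each gene. No genome came with the series, so no coordinates are given.

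The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named, for each exposure, the 10 largest rises and 10 largest falls among genes past the threshold, filled up with the smallest unadjusted p where fewer passed, up to 4 members of each list described, and a fixed set of hypothalamic peptides and TTR. For the difference between the arms and the vehicle groups it named the 5 smallest unadjusted p values in each direction. A few genes that meet the rule are left unnamed. Of 33 gene lists with 707 genes, 161 genes were measured, and 19 lists had at least 5 measured members and were tested with camera at a preset correlation of 0.01. An estimated correlation and fry were alternatives. Camera compares a list with all other named genes, whereas fry asks whether a list's genes move one way on balance.

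Slides were read from the file headers. The arrays numbered 1, 2 and 3 of each group lay on slides 1, 2 and 3, apart from maternal vehicle replicate 3 on slide 4. Fetal vehicle replicate 4 shared slide 3, and fetal triclosan replicate 4 lay alone on slide 5, scanned on its own day. Values with the slide as a block and differences within slides are given beside the results. The slide block leaves fetal triclosan replicate 4 without a partner, so direct values under it rest on fetal triclosan replicates 1 to 3. The other alternatives were normexp background correction (offset 50), quantile normalisation, median scaling, no probe filter, a stricter filter, outlier spots kept, the authors' values, only the groups compared, the replicate number as a block, array weights, a variance trend with robust fitting, and each array left out in turn.

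The fit was tested on simulated data with known changes. Values were drawn independently for each probe and array, with 1 spread per probe for all groups and no trend with brightness. Such data meet the assumptions of the fit, so the shares below may not hold for the real arrays. In 13595 simulated probes of the direct comparison it recovered 59% of changes of 1 on the log2 scale and 87% of changes of 2, with 4 false calls. In the indirect comparison it recovered 36% and 85%, with 8 false calls. For the direct counts, all 35 splits of the 8 fetal arrays into 4 and 4 were also fitted. The number of arrays limits the precision of every value.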

Results

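The data describe the hypothalamus of late-gestation fetal sheep after triclosan, an antibacterial additive of personal care products, was infused into the fetus or into the ewe. The direct arm had vehicle (n = 4) and triclosan (n = 4) infused into the fetus, and the indirect arm had vehicle (n = 2 independent arrays of 3 deposited) and triclosan (n = 3) infused into the ewe. The median processed signal per array was 315 to 380 with fetal vehicle, 236 to 307 with fetal triclosan, 351 to 354 with maternal vehicle and 284 to 376 with maternal triclosan. Between 83.3% and 90.1% of spots were well above background, and 0 spots were saturated. The first principal component (26.3% of the variance) placed the fetal triclosan arrays at 15.4 to 62.3 and all other arrays at −28.2 to −5.04. Values below are log2 differences between triclosan and vehicle with the standard error (SE) of the limma fit.

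The direct arm asks which hypothalamic transcripts differ when triclosan is infused into the fetus itself. KDR, the main signalling receptor for vascular endothelial growth factor, fell by 1.57 on the log2 scale (SE 0.17, n = 4 and 4), with all 4 of its probes called. CD93, a receptor of endothelial and myeloid cells, fell by 2.10 (SE 0.40), and ZO2, a tight junction scaffold, fell by 1.76 (SE 0.33). HSP70.1, an inducible heat shock protein, fell by 1.48 (SE 0.26) and HSP90AA1, an abundant cytosolic chaperone, by 0.80 (SE 0.13). The glucocorticoid receptor NR3C1 rose by 0.69 (SE 0.16), and the ribosomal protein gene RPL34 rose by 0.79 (SE 0.11).

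The other large falls came from several kinds of gene. MGLUR3, a metabotropic glutamate receptor, fell by 1.89 (SE 0.32), and FGFR3, a fibroblast growth factor receptor of glia, by 1.61 (SE 0.35). PPARGC1A, a coactivator of mitochondrial genes, fell by 1.21 (SE 0.23). FBXO32, a ubiquitin ligase of the atrophy response, fell by 1.23 (SE 0.27). PAPP-A, a protease of insulin-like growth factor binding proteins, was not well above background on any fetal triclosan array. In the main processing it was at least 1.51-fold higher with vehicle (adjusted p = 0.0383). PAPP-A lost the call under 6 processing alternatives and in 5 fits without 1 array. Its log2 value was −0.24 with the authors' values and 0.04 with normexp correction. The largest rise was that of CXCL10, an interferon-induced chemokine, at 1.76 (SE 0.52, adjusted p = 0.0363). CXCL10 lost the call with only the fetal groups in the fit (adjusted p = 0.0929) and with the replicate number as a block (0.0597). It also lost the call without any 1 of fetal vehicle replicates 2 to 4 and fetal triclosan replicates 1 to 3 (0.0713 to 0.102), and without maternal vehicle replicate 2. AHSP, the chaperone of alpha haemoglobin, rose by 0.94 (SE 0.28). MIF, a cytokine, rose by 0.73 (SE 0.20), MGLUR4, another metabotropic glutamate receptor, by 0.71 (SE 0.13), and MT3, a brain metallothionein, by 0.71 (SE 0.19). AHSP and MIF lost the call in several fits too, among them those without fetal vehicle replicate 2 or 3 and fetal triclosan replicate 1 or 2, and MIF with quantile normalisation (0.55) and the authors' values (0.58). The ribosomal protein gene RPS26 rose by 0.77 (SE 0.13).

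**Figure D1:**
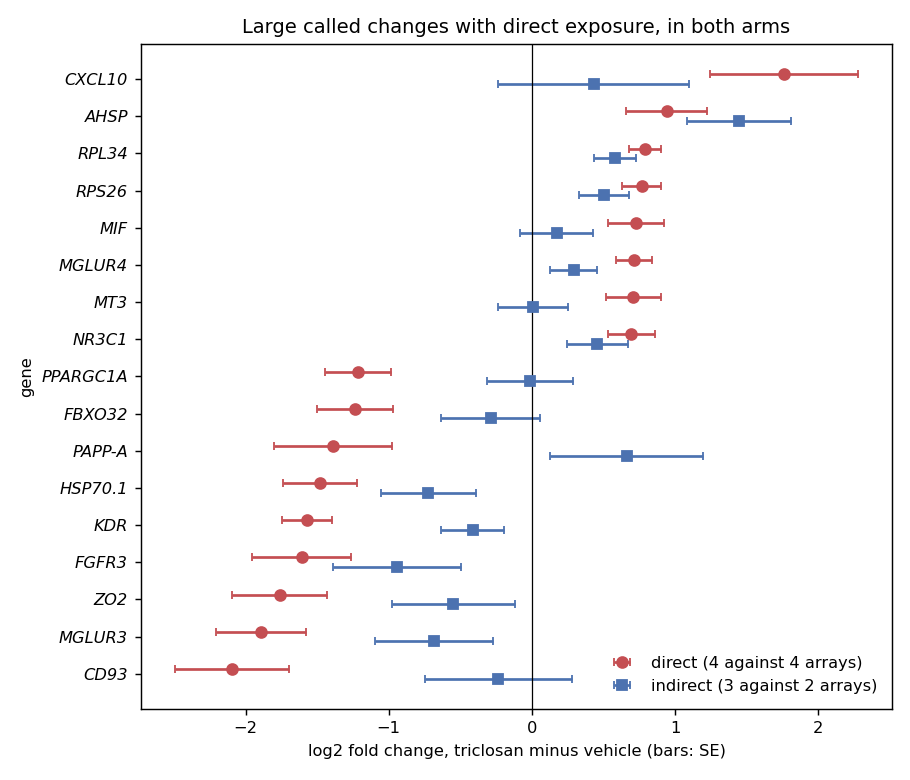
Log2 fold change of 17 genes with large called rises or falls with direct exposure (circles, 4 against 4 arrays), with the same genes in the indirect arm (squares, 3 against 2 arrays) and bars for the SE. In the indirect arm 16 of the 17 genes lay on the same side of 0, the exception being PAPP-A, and 0 of the 17 passed the test there.

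In limma's test, 2490 of 13740 probes passed the adjusted threshold with direct exposure, 935 higher and 1555 lower with triclosan, and 4553 passed an unadjusted p of 0.05, where chance gives 687. Of 893 named genes, 131 passed, 50 higher and 81 lower. A change of over 2-fold was seen at 508 called probes, 48 higher and 460 lower. The lowest adjusted p was 0.00140. With the slide as a block, which sets fetal triclosan replicate 4 aside, 2972 probes passed, 1108 of them higher. The fit without that array called 2944, so the block is not a slide adjustment of all 4 triclosan arrays. Within slides 1, 2 and 3 the called probes kept their direction in 99.92%, 99.84% and 99.88% of cases. These shares are high by selection because the probes were called from these same arrays. Of 36 called genes that met the naming rule, ABCG2, AHSP, MT3, PAPP-A and RPL14 lost the call with the slide block, and PAPP-A turned to 0.04 with normexp correction. The split between rises and falls depended on the scaling, since median scaling gave 2174 higher and 946 lower probes and moved the median of all probes from −0.09 to 0.13, and the count fell to 1654 without fetal vehicle replicate 1, 1223 without fetal vehicle replicate 3 and 1275 with only the fetal groups in the fit.

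Dim and bright probes moved apart in the direct arm. The median log2 difference was −0.29 in the dimmest decile of probes and 0.24 in the brightest, and after quantile normalisation these were −0.07 and 0.02. In the main analysis 381 probes of the brightest decile were called higher against 19 lower. The difference between probes near the 5′ end and probes near the 3′ end of 24 transcripts, a sign of RNA integrity, differed by −0.11 between triclosan and vehicle (exact permutation p = 0.2, two-sided). The highly expressed ribosomal protein genes and the dim receptors KDR and CD93 lie on the sides of this trend on which their values fell, while HSP90AA1 and HSP70.1 are among the brighter probes and fell against it.

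**Figure D2:**
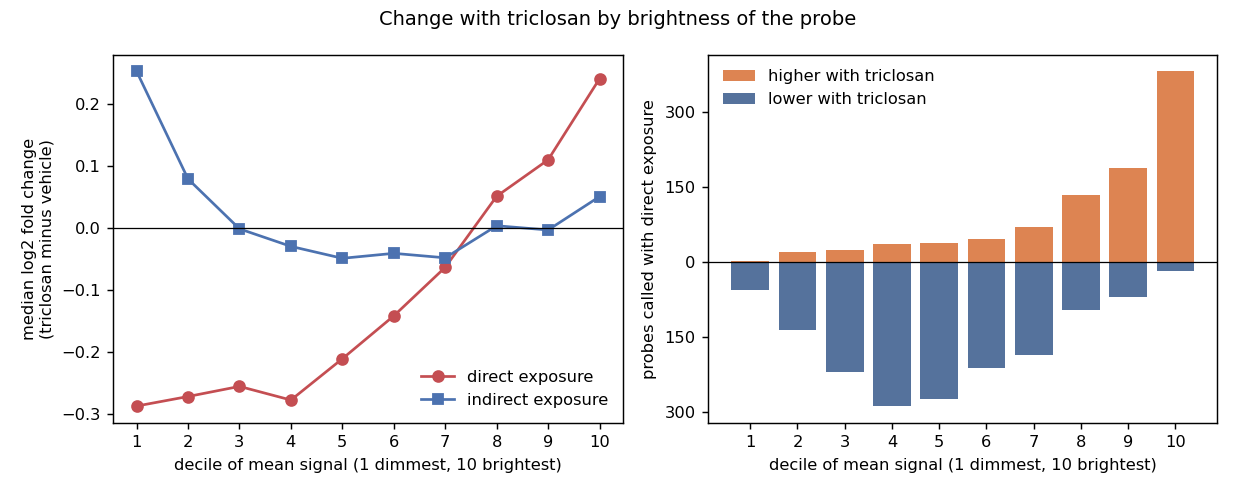
Left, median log2 fold change (triclosan minus vehicle) in each decile of probes by mean signal, for direct exposure (circles) and indirect exposure (squares). Right, number of probes called with direct exposure in each decile, higher above the line and lower below it. The direct medians run from −0.29 in the dimmest decile to 0.24 in the brightest, and the indirect median of the dimmest decile is 0.25.

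Of the 4 measured endothelial and pericyte genes, 2 fell and 0 rose, also adjusted over the list alone. FLT1, a decoy receptor for vascular endothelial growth factor, fell by 1.19 (SE 0.25, 1 of its 2 probes called) but was well above background on only 1 of 4 fetal triclosan arrays, and its value was −0.04 with normexp correction and −0.38 with the authors' values. PECAM1, an adhesion molecule of endothelial junctions, had a value of −0.26 and TIE1, a receptor of angiopoietin signalling, of 0.06, and neither passed. The median of this list was −0.72, or −0.63 with the slide block, and −0.72, −0.76 and −0.48 within slides 1, 2 and 3. Among astrocyte genes FGFR3 was the 1 of 4 that passed, and its value was −0.40 with normexp correction. Of 3 microglia genes, ITGAM, an integrin of phagocytes, fell by 0.95 (SE 0.29), and it lost the call under 5 processing alternatives and in 9 fits without 1 array, those without each fetal vehicle array, each maternal vehicle array, fetal triclosan replicate 1 or 2 and maternal triclosan replicate 1. FCER1G, an Fc receptor chain, had a value of 0.46 and rose adjusted over that list alone.

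**Figure D3:**
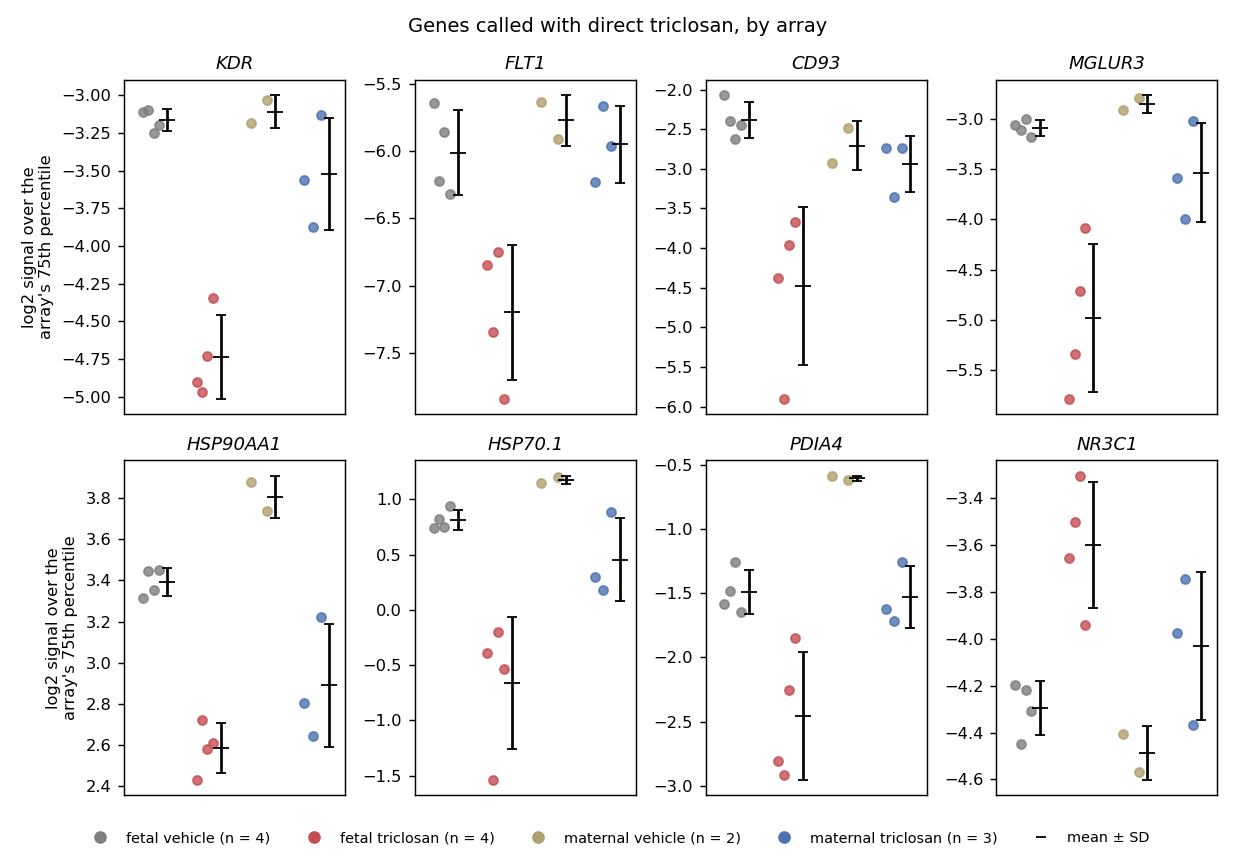
Log2 signal relative to the 75th percentile of the array for 8 genes called with direct exposure, by array (points) with group mean and SD (bars), for fetal vehicle (n = 4), fetal triclosan (n = 4), maternal vehicle (n = 2) and maternal triclosan (n = 3). KDR lies between −4.97 and −4.35 on the fetal triclosan arrays and between −3.25 and −3.10 on the fetal vehicle arrays.

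Of the 6 measured heat shock and unfolded protein genes, 3 fell, or 4 adjusted over the list alone, and 0 rose. PDIA4, a disulfide isomerase of the endoplasmic reticulum, fell by 0.96 (SE 0.22) and HSPA5, its main luminal chaperone, by 0.64 (SE 0.16). XBP1, a transcription factor of the unfolded protein response, had a value of −0.58 (adjusted p = 0.101). XBP1 was called lower with array weights (adjusted p = 0.0225) and the authors' values (0.0456). The slide block (−0.77, adjusted p = 0.0148) and the fit without fetal triclosan replicate 4 (0.0111) also called it, but both set that array aside. HSPA5 lost the call with median scaling (−0.42) and without fetal vehicle replicate 3 (−0.64). The list median was −0.61, or −0.74 with the slide block, and −0.74, −0.78 and −0.46 within slides 1, 2 and 3. Camera gave an adjusted p of 0.121 for this list, below the threshold with normexp (0.00421), quantile normalisation (0.0492), the authors' values (0.00968) and without fetal vehicle replicate 1 (0.0491). HSP70.1, MGLUR3 and ZO2 carry names of the array design and counted in no list.

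Of 9 measured genes of fatty acid synthesis and oxidation, 4 fell and 0 rose, with 1 rise adjusted over the list alone. ACLY, which makes cytosolic acetyl-CoA, fell by 0.93 (SE 0.23), CPT1A, which carries fatty acids into mitochondria, by 0.89 (SE 0.21), and SCD, the desaturase of saturated fatty acids, by 0.72 (SE 0.17), beside PPARGC1A. ACLY lost the call without fetal vehicle replicate 3. CPT1A lost it with only the fetal groups in the fit (adjusted p = 0.0543) and with the replicate number as a block (0.0803). The fatty acid list median was −0.66, or −0.51 with the slide block, and −0.13, −0.51 and −0.32 within slides 1, 2 and 3, with a camera adjusted p of 0.448.

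Of 5 measured ribosomal protein genes, 3 rose and 1 fell, with 4 rises adjusted over the list alone. RPS25 rose by 0.44 (SE 0.11) and RPL14 by 0.47 (SE 0.13), while RPL32 fell by 0.69 (SE 0.19). Quantile normalisation left RPS25 at 0.15 and RPL14 at 0.20, and the authors' values left RPS25 at 0.0028 and RPL14 at 0.12, each without a call, and RPL32 lost the call with median scaling (−0.47). Camera gave an adjusted p of 0.0925, which passed with outlier spots kept (0.00293), with only the fetal groups (0.0285), without fetal vehicle replicate 1 (0.0491) and without maternal triclosan replicate 2 (0.0263). The list median was 0.44, or 0.37 with the slide block, and 0.53, 0.41 and 0.22 within slides 1, 2 and 3. MT3 and TXN, a thiol reductant that rose by 0.56 (SE 0.16), were 2 of 3 oxidative stress genes, and all 3 rose adjusted over the list alone. SOD2, the mitochondrial superoxide dismutase, had a value of 0.51. MT3 and TXN lost the call with quantile normalisation (0.40 and 0.28), the authors' values (0.34 and 0.21) and only the fetal groups in the fit, and TXN also with normexp correction and array weights. Of the 13 fits without 1 array TXN lost it in 10, all but those without fetal triclosan replicate 1 and maternal triclosan replicates 2 and 3, and MT3 in 3, those without fetal vehicle replicate 1 or 3 and fetal triclosan replicate 1.

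In the remaining lists with a call, 1 gene each passed. NR3C1 rose in the stress axis list (9 measured), where CRHR1, the receptor for corticotropin-releasing hormone, had a value of −0.93 (adjusted p = 0.0673) and was called lower with the slide block (−0.78, adjusted p = 0.0326), the stricter filter (0.0496), all 14 arrays (0.0484) and without fetal vehicle replicate 1 (0.0437). ABCG2, an efflux pump of the blood-brain barrier, rose by 0.46 among 7 xenobiotic genes, and it lost the call with quantile normalisation (0.30), the authors' values (0.31), only the fetal groups, the slide block (0.39) and 9 of 13 fits without 1 array, those of each fetal array but fetal triclosan replicate 3 and of maternal triclosan replicates 1 and 3. ABCB1, another efflux pump, had a value of −0.49 and passed as a fall adjusted over the list alone. CXCL10 rose among 6 interferon genes. JUND, a subunit of the AP-1 transcription factor, fell by 1.14 (SE 0.22) among 4 immediate early genes, with values of −0.31 for FOS (3 of its 4 probes called lower), −0.30 for JUNB and 0.32 for EGR1, whose other probe was at −0.55. ARNT2, a hypothalamic transcription factor, fell by 0.77 among 3, and PTGDS, a prostaglandin synthase of the meninges, rose by 0.55 among 7 connective tissue genes. ARNT2 had −0.17 with normexp correction (adjusted p = 0.556) and −0.32 with the authors' values (0.0639), PTGDS had 0.24 with quantile normalisation (0.292) and 0.10 with the authors' values (0.690), and both lost the call in several fits without 1 array, among them that without fetal vehicle replicate 3. AHSP rose among 3 erythroid genes. There HBB, beta haemoglobin, had a value of 1.32 (adjusted p = 0.0604) and CA1, an erythrocyte carbonic anhydrase, of 1.14. HBB passed with all 14 arrays, median scaling, the stricter filter, the variance trend and the replicate number as a block. It also passed without fetal vehicle replicate 4 or maternal triclosan replicate 3 (adjusted p 0.0304 to 0.0486 over these fits). All 3 erythroid genes rose adjusted over the list alone (list median 1.14, or 0.89 with the slide block and 1.19, 1.28 and 0.49 within slides 1, 2 and 3).

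The hypothalamic peptide genes did not pass in the direct arm and varied widely between arrays. GHRH, which releases growth hormone, had a value of 2.32 (SE 0.91, adjusted p = 0.101), GNRH1, which releases gonadotropins, 1.61, and AGRP, an appetite-stimulating peptide, 1.17. SST, which inhibits growth hormone, had 1.14, GAL (galanin) 1.06, TAC3 (neurokinin B) 0.90, POMC, the precursor of melanocortins, 0.65, NPY (neuropeptide Y) 0.64, PMCH (melanin-concentrating hormone) 0.52, and OXT (oxytocin) 0.43. The mean of these 10 genes was −0.62 to −0.33 on fetal triclosan replicates 1 to 3 and −2.50 on replicate 4, against −2.58 to −1.05 on the fetal vehicle arrays. Without fetal triclosan replicate 4, limma called GHRH at 3.14 (adjusted p = 0.0196), SST at 1.68 (0.0131), GAL at 1.5 (0.0137), TAC3 at 1.31 (0.00924) and NPY at 1.26 (0.0219). The slide block, in which replicate 4 has no partner, called these 5 genes and AGRP (2.43, adjusted p = 0.0445), and GHRH also passed without fetal vehicle replicate 4 (3.04).

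**Figure D4:**
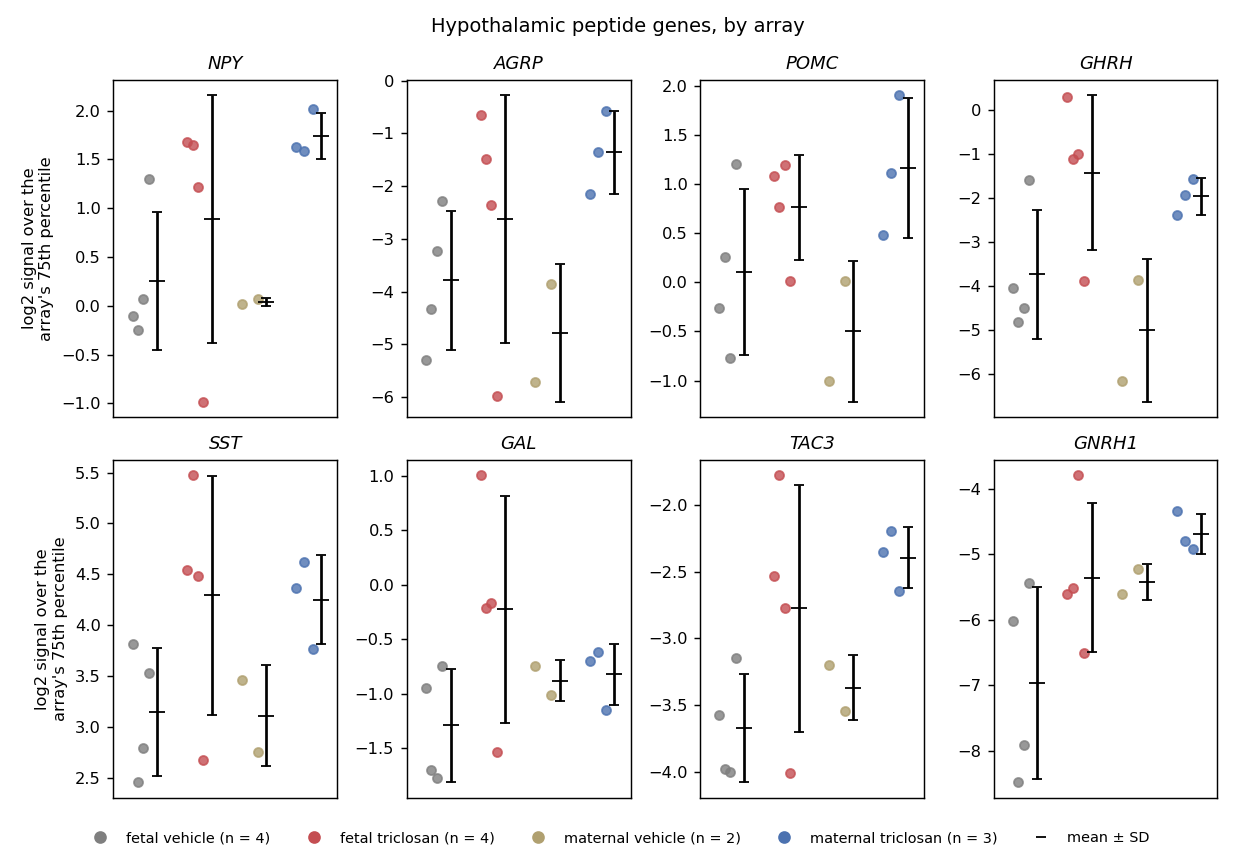
Log2 signal relative to the 75th percentile of the array for 8 hypothalamic peptide genes, by array (points) with group mean and SD (bars), for fetal vehicle (n = 4), fetal triclosan (n = 4), maternal vehicle (n = 2) and maternal triclosan (n = 3). Over 10 peptide genes the array means were −0.86 to −0.62 with maternal triclosan and −2.26 to −1.90 with maternal vehicle.

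Camera called 0 of 19 lists in the direct arm, with 2 at an unadjusted p of 0.05, 0 with an estimated correlation and 3 with fry (heat shock, fatty acid and ribosomal lists, each at an adjusted p of 0.0153). With the slide block the lowest camera adjusted p was 0.124. No member passed in the lists of orexigenic (8 measured), anorexigenic (6), reproductive (10), growth hormone and prolactin (10), thyroid (5), estrogen (6), hypoxia (8), mitochondrial (1), inflammation (10), glutamate and GABA (5), oligodendrocyte (1), ependymal (3), choroid plexus (3), pituitary (6), circadian (6) and cell cycle genes (5). PCNA, a replication clamp, had a value of 0.48 and rose adjusted over the cell cycle list alone. TTR, the thyroid hormone carrier of the choroid plexus, had a value of 0.76 (SE 1.00). No gene of the neuron and the thalamus lists was measured under a listed symbol. Median and camera direction had opposite signs for the growth hormone, estrogen, hypoxia, pituitary, connective tissue, cell cycle and circadian lists, and median and mean for the growth hormone and xenobiotic lists.

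The indirect arm asks what the hypothalamus shows when triclosan is infused into the ewe. No named gene passed the adjusted test, and the values below are those with the smallest unadjusted p or of fixed interest (n = 3 and 2). EAAT2, the main glutamate transporter of astrocytes, had a value of −1.44 (SE 0.23, adjusted p = 0.227), HSP90AA1 of −0.92 (SE 0.17, adjusted p = 0.246) and PDIA4 of −0.93 (SE 0.28). Among higher values, AHSP had 1.45 (SE 0.36), ACACA, the rate-limiting enzyme of fatty acid synthesis, 1.39 (SE 0.38), and LCK, a T cell kinase, 0.92 (SE 0.23).

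Other lower values were those of PRL (prolactin, −1.57, or −0.57 without maternal vehicle replicate 2), ADORA3, an adenosine receptor (−0.93), SOD2 (−0.84), COX5A, a subunit of cytochrome oxidase (−0.83), ATP6V1B2, a proton pump subunit (−0.82), ACVR1, an activin and bone morphogenetic protein receptor (−0.71), GGCX, the vitamin K-dependent carboxylase (−0.66), and FCGR1A, an Fc receptor of phagocytes (−0.56). Other higher values were those of HBB (1.80), CALML4, a calmodulin-like gene (0.82), DCN, a proteoglycan of connective tissue (0.82), IGFBP6 (0.76), TIMP1, an inhibitor of matrix proteases (0.73), RPL34 (0.58), ATF4, a stress transcription factor (0.46), and H3F3A, a histone variant (0.40). The second probe of HBB had a value of −0.43. KDR had a value of −0.41, and 2 of its 4 probes lay above 0.

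Several peptide genes had high values with large errors in this arm, GAL not among them. AGRP had 3.42 (SE 1.35, adjusted p = 0.480), GHRH 3.04 (SE 1.18), NPY 1.70 (SE 0.69), POMC 1.66 (SE 0.59), SST 1.14, TAC3 0.97, GNRH1 0.73, PMCH 0.63, OXT 0.44 and GAL 0.06. With normexp correction GNRH1 turned to −0.09 and PMCH to −0.07. The pituitary marker CGA, the common alpha subunit of glycoprotein hormones, had a value of 3.83 (SE 1.66), and TTR had −1.51 (SE 1.29).

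With indirect exposure camera called 2 of the 19 lists, heat shock and unfolded protein genes lower (6 measured, median −0.50) and cell cycle genes higher (5 measured, median 0.57, 5 of 5 above 0), each at an adjusted p of 0.0386 and each at adjusted p = 0.761 with an estimated correlation. Fry called 0 lists, with adjusted p of 0.303 and 0.481. In the heat shock list HSPA5 had a value of −0.48 and XBP1 of −0.46 beside HSP90AA1 and PDIA4, 0 of its members passed over all probes, and 2 fell and 1 rose adjusted over the list alone. In the cell cycle list AURKA, a mitotic kinase, had 0.88, CDK1, the mitotic cyclin-dependent kinase, 0.82, TYMS, which makes thymidylate, 0.57, and PCNA 0.44, and 0 passed, also over the list alone. The heat shock median was −0.55 with the slide block and −0.71 within both slide 1 and slide 2, and the cell cycle median was 0.54 with the block and 0.71 and 0.60 within them, with camera adjusted p of 0.0256 and 0.0368 under the block. The heat shock call was lost with normexp (0.385), the authors' values (0.224), only the maternal groups in the fit (0.272), the mean of probes per gene (0.0549) and without fetal triclosan replicate 1 (0.297). The cell cycle call was lost with normexp (0.0557), median scaling (0.0525) and without fetal triclosan replicate 2 (0.0507) or maternal triclosan replicate 1 (0.114) or 3 (0.0598). Both calls were lost without fetal vehicle replicate 1 or 2, either maternal vehicle array, fetal triclosan replicate 3 or maternal triclosan replicate 2. Array weights and the variance trend could not change any list call, since camera was run without them.

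In limma's test 0 of 13740 probes passed the adjusted threshold with indirect exposure (lowest adjusted p 0.227), and 1324 passed an unadjusted p of 0.05, 677 higher and 647 lower. With the slide block 0 passed and 2092 had an unadjusted p under the threshold. Over the list alone, genes passed in 6 lists, among them AHSP and HBB in the erythroid list (2 rose) and PRL in the pituitary list (1 fell, a value that rests largely on maternal vehicle replicate 2). With all 14 deposited arrays 12 probes passed, among them EAAT2 and HSP90AA1, and with array weights 356 passed, 182 of them higher. Normexp correction moved the median of all probes in this arm from 0.01 to −0.15. The median and the camera direction had opposite signs for the interferon list, and the median and the mean for the fatty acid list.

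The difference between the arms sets the direct against the indirect value, at doses and in compartments that also differ. No named gene passed. SOD2 had a difference of 1.36 (SE 0.34, adjusted p = 0.228), ADORA3 1.19, EAAT2 1.15 and ENDOG, a mitochondrial nuclease, 0.60. On the lower side were MYD88, an adaptor of innate immune receptors, at −1.56 (SE 0.36, with its second probe at 0.41), KDR at −1.16 (SE 0.28), IKKBETA, a kinase of the NF-kappaB pathway, at −1.14, and NKX2.2, a neural transcription factor, at −0.82. In limma's test 0 probes passed (lowest adjusted p 0.193) and 2013 had an unadjusted p under 0.05, with 0 and 1917 under the slide block. Without fetal triclosan replicate 3 there were 12, which were chosen for mention after their values were seen and included SOD2 (1.59) and a second probe of KDR (−1.17). Camera called 0 of 19 lists (lowest adjusted p 0.804, 0 at an unadjusted p of 0.05), and fry called 0, with 1 at an unadjusted p of 0.05. The 131 genes called in the direct arm are therefore not shown to differ from their values in the indirect arm.

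Between the vehicle groups no gene passed. PRL was 2.02 higher in maternal than in fetal vehicle (SE 0.45, adjusted p = 0.999), with the 2 maternal arrays at −3.19 and −1.19, and ADORA3 0.92, PDIA4 0.89, IL1B, an inflammatory cytokine, 0.57 and FCGR1A 0.46 higher. TAC1, the precursor of substance P, had a value of −0.68, PTH-RP, a calcium-regulating peptide, −1.07, DERL1, a factor of protein quality control, −0.52 and FGF1, a fibroblast growth factor, −0.51. PAPP-A was not well above background on the maternal vehicle arrays and at least 2.12-fold higher with fetal vehicle. In limma's test 0 probes passed (lowest adjusted p 0.884) and 449 had an unadjusted p under 0.05, where chance gives 687. The slide block gave 0 and 703.

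The values of the arms were compared across 13600 probes, which are not independent replicates. Pearson's r was 0.162 and Spearman's rho 0.190, and 700 relabellings within the arms gave permutation p values of 0.403 and 0.360 (two-sided). Of the 2490 probes called with direct exposure, 1945 (78.1%) had the same direction in the indirect arm, 698 of 935 rises and 1247 of 1555 falls. The median indirect value was 0.13 for the rises and −0.24 for the falls. Of the 10 labellings of the maternal arrays 2 gave a share as high, and the design cannot go below a share of 0.1.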

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

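The tests of quantile normalisation, slide, 5′ and 3′ probes, peptide correlation and maternal vehicle levels below were chosen only after the result was seen, while the splits of the arrays, the exchange of labels and the brightness of the chaperone genes were set before.

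In 3 of 124 groups of 4 arrays tested, 1 array lay far from the others, where chance gives about 1 in 20, or 6.2. JUND was at −2.14 on fetal triclosan replicate 2 and at −1.15 to −1.05 on the other 3 arrays, a gap of 0.912 of the range. ITGAM was at −5.70 on the same array and at −4.86 to −4.71 on the others (0.846). The median processed signal was 315 on fetal vehicle replicate 2 and 377 to 380 on the other fetal vehicle arrays (0.950).

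The direct count was compared with all 35 splits of the 8 fetal arrays into 4 and 4. The real split was the 1 of 35 with as many probes past the adjusted threshold (2490, highest other 2) and the 1 of 35 with as many at an unadjusted p of 0.05 (4553, highest other 2796). A share of 1 of 35 is under the 0.05 set beforehand, and it is the lowest that 35 splits allow. These splits exchange arrays across slides, so they do not exclude chance under the slide layout. Exchanges within slides alone leave 12 labellings, too few for a share under 0.05 (1 of 12 as large, highest other 0 adjusted and 2253 unadjusted). For the gene lists the real count of 0 fixes the outcome (35 of 35 splits gave as many, highest other 3), so the splits say nothing about chance there.

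With direct exposure dim probes such as those of KDR and CD93 were lower and bright probes such as those of RPS26 and RPL34 higher. These named genes kept the call with quantile normalisation, so the explanations below concern the trend over all probes. Over all probes the median of the brightest decile lay 0.53 above that of the dimmest. A trend with brightness between arrays may have made this and stays open, since the difference was 0.090 after quantile normalisation, which removes a real trend as well as a technical one. For the slide as the whole cause, the difference was 0.38 under a slide block and 0.59, 0.30 and 0.30 within slides 1, 2 and 3. Each of these slides holds both fetal groups, so a shift shared by all arrays of a slide cancels there. The difference was above 0 on each slide but not beyond the spread set for the test, which leaves this formally open. Degraded RNA in the exposed fetuses stays open, since the 5′ minus 3′ signal of 24 transcripts differed by −0.1108 between the groups (exact permutation p = 0.2, two-sided), which does not show that they were alike. An effect of triclosan also stays open, as untested against these.

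The mean of 10 peptide genes, GHRH, AGRP, NPY and SST among them, was −0.86 to −0.62 on the maternal triclosan arrays and −0.62 to −0.33 on fetal triclosan replicates 1 to 3, but −2.50 on fetal triclosan replicate 4 and −1.05 on fetal vehicle replicate 4. GAL, also among the 10, did not share this in the indirect arm (0.06). An exchange of the arrays numbered 4 is argued against. Over 2550 probes fetal triclosan replicate 4 lay at 0.5496 between vehicle (0) and triclosan (1) and fetal vehicle replicate 4 at 0.2007, and the exchanged groups gave 0 adjusted and 2253 unadjusted limma calls. A share of peptide-rich tissue that differed between dissected pieces is a candidate explanation. The 10 genes correlated within groups with a mean r of 0.5463, where the upper bound among matched lists was 0.177. All 10 lay below their group mean on fetal triclosan replicate 4 and above it on fetal vehicle replicate 4. The correlation was thus tested on the genes and arrays in which the pattern was seen. A response to triclosan that 1 fetus lacked could also raise it and stays open as well, so the correlation does not favour either.

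The chaperone genes HSP90AA1, PDIA4, HSPA5 and XBP1 were lower with triclosan in both arms, though only the first 3 passed, and only in the direct arm, where XBP1 passed with the slide block (−0.77, adjusted p = 0.0148). They are 4 of 6 measured members of their list, and of the others ATF4 was at 0.46 in the indirect arm and DDIT3, named after its value was seen, at 0.27 in the direct arm. The brightness trend is argued against, since the list median lay at percentile 0.22 of 10000 lists matched on brightness in the direct arm and 0.1 in the indirect arm. High levels on the 2 maternal vehicle arrays alone may explain the indirect value. The list mean was 0.66 and 0.51 there against 0.21 to 0.32 on the fetal vehicle arrays, and maternal triclosan minus fetal vehicle was −0.1497 (exact permutation p = 0.1143, two-sided), which leaves this open. An effect of triclosan stays open too.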

How the results depend on the processing

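The fit of all 14 deposited arrays was chosen only after the result was seen, and the other alternatives were planned.

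Of 36 genes that met the naming rule and were called with direct exposure, 18 kept the call under every processing alternative and without each array, among them KDR, CD93, HSP90AA1, HSP70.1 and PDIA4 (lower) and NR3C1, RPL34 and RPS26 (higher). Of 465 processing values of these genes 406 kept direction and call, 58 lost the call and 1 reversed, PAPP-A at 0.041 with normexp. Without an array 388 of 465 kept both and 77 lost the call. In the indirect arm normexp reversed GNRH1 (−0.090) and PMCH (−0.069).

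The direct count was 1275 with only the fetal groups in the fit, and 1733 to 3120 under quantile normalisation, normexp, the authors' values, median scaling, the filters, array weights, the variance trend, the slide block and 14 arrays. The fit of the fetal groups alone has fewer arrays and leaves out the spread of the maternal groups, which the main fit pools. The median SD of a probe within a group was 0.33 with fetal triclosan and 0.20 with fetal vehicle. It was 0.13 with maternal vehicle and 0.19 with maternal triclosan, so pooling may make the direct SEs too small. Of the 2490 probes, 1393 were kept with quantile normalisation, 1688 with normexp and 1389 with the authors' values. Higher probes made up 37.55% of calls, but 46.51% with normexp and 69.68% with median scaling.

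Direct exposure had 3 lists called with fry and 1 each with normexp, quantile normalisation, outlier spots kept, the authors' values and only the groups compared. Indirect exposure had 2 lists in the main analysis, 0 with an estimated correlation, fry or normexp, and 1 with the mean of probes per gene, median scaling, the authors' values or only the groups compared. The list tests did not take in array weights or the variance trend, so under these alternatives they repeat the main result. The cause was not tested.

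For indirect exposure limma called 12 probes with all 14 arrays and 356 with array weights. At an unadjusted p of 0.05 there were 2252 with all 14 arrays, 2180 with only the groups compared, 2092 with the slide block and 3359 with array weights. The 14 arrays count a mixture of 2 arrays as a further array, which narrows the spread by construction. The difference between the arms had 4 calls with all 14 arrays and 1 with quantile normalisation (probe A_70_P045111 at 2.29, chosen after its value was seen). The cause of the other changes was not tested.

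Without each array in turn the direct count was 1223 (without fetal vehicle replicate 3) to 2955 (without fetal triclosan replicate 3), and 1654 without fetal vehicle replicate 1. The direct lists called were 0 to 2. Indirect calls were 0 to 2, unadjusted 551 (without maternal vehicle replicate 1) to 1799, and lists 0 to 2. The difference had 0 to 12 calls (12 without fetal triclosan replicate 3) and the vehicle groups 0 to 2 (2 without maternal vehicle replicate 2). TTR in the direct arm ran from −0.11 (without fetal triclosan replicate 3) to 1.71, and GAL in the indirect arm from −0.077 (without maternal vehicle replicate 2) to 0.22, with −0.0031 and −0.05 without maternal triclosan replicates 1 and 2. Without a maternal vehicle array the lone one is assumed to vary like the other groups.

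Same-numbered fetal arrays correlated at 0.13, 0.118 and 0.264 for numbers 1 to 3, which share a slide, and at −0.17 for number 4, and maternal ones at −0.0839 and −0.0764, so the numbers as a whole were not taken as pairs. Fetal triclosan replicates 1 to 3 and fetal vehicle replicates 1 and 3 matched their own number best, fetal vehicle replicate 2 did not. With the number as a block, 1665 probes were called with direct exposure, 2 with indirect exposure and 2 for the difference, the last 2 counts being probes of ASIP. Of the 36 called genes that met the naming rule, ABCG2, AHSP, ARNT2, CPT1A, CXCL10, MIF, MT3, PAPP-A, PTGDS and TXN lost the call there. This block also gave 1 call between the vehicle groups, ASIP at 10.37 (A_70_P027462), which has no meaning. The blocks lie within each arm, so they cannot be told apart from a difference between the arms' vehicle groups. On the arrays themselves that probe read 2.42 and 2.79 with maternal vehicle and 1.38 to 3.08 with fetal vehicle. Dim signals limit PAPP-A and FLT1, which were near background with triclosan.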

Other observations

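The genes below were chosen only after the result was seen, no test of an explanation was run on them, and their adjusted p values come from the planned limma test.

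ASIP, the agouti signalling peptide that blocks melanocortin receptors, was measured by 2 probes. They read −3.22 and −3.28 (A_70_P027461) and −6.73 and −6.58 (A_70_P027462) on maternal triclosan replicates 1 and 2, and 3.72 to 5.38 and 1.38 to 3.30 on the other 11 arrays. The indirect values were −5.25 (SE 1.87, adjusted p = 0.459) and −6.09 (SE 2.14, adjusted p = 0.458). Without maternal triclosan replicate 3 they were −8.03 and −9.26, each at an adjusted p of 1.01e-05. The residual SD was 2.30 and 2.63, where the median over probes was 0.27 and the 99th percentile 1.33.

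OVAR-DQA1, an antigen-presenting molecule of the MHC class II, ran from −9.46 to −0.54 across the 13 arrays at probe A_70_P016751 and from −1.78 to −0.88 at probe A_70_P053731. CGA, the alpha subunit of pituitary glycoprotein hormones, ran from −6.60 to 0.30 at probe A_70_P039421, with 0.30 on fetal vehicle replicate 4, 0.09 and −0.20 on maternal triclosan replicates 2 and 3 and −0.67 on fetal triclosan replicate 1. HSD11B2, which inactivates cortisol, read −2.44 and −2.30 at its 2 probes on fetal triclosan replicate 3.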
